A study of Homo sapiens with 16 samples.

How the data were processed

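The dH1f fibroblasts, differentiated from the H1 line, were infected 2 times with a hairpin virus and selected with puromycin, and RNA was taken at passages 8 to 12, before or 6 days after infection with the reprogramming factors, per the labels. RNA was extracted with Directzol columns, libraries were made with the NEBNext Ultra kit and sequenced on a NextSeq 500 as paired reads of 75 bases. The deposited values are raw counts per Ensembl gene ID, which the authors made from trimmed and aligned reads; the submitters' processing notes name cutadapt, TopHat2, SAMtools and the GRCh37 build, without versions. The counting tool, and whether the counts respect strand, are not given in the sources used here. Antisense and overlapping transcripts were therefore not separated, and genes with near-identical copies (keratins, histones, ribosomal proteins) may exchange reads. Counts cannot tell the delivered POU5F1, SOX2, KLF4 and MYC from the cells' own.

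Each of the 16 libraries held 57373 IDs, of which 51831 received a symbol. Names, gene types and gene spans came from GENCODE 29, used for names, types and lengths only. The libraries formed 6 groups by hairpin and time. Replicate 2 is absent from both SETD2 hairpin groups before OSKM, so these had 2 libraries and all other groups 3. Total counts were 21764800 to 32510600 per library. The common biological coefficient of variation was 8.96%.

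Genes were kept by edgeR's expression filter within groups (18302 genes), scaled by TMM (lowest factor 0.876) and tested with edgeR 4.0.16 in R 4.3.3 by the robust quasi-likelihood F test, with all 16 libraries in 1 model of 6 groups. P-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. Standard errors were derived from the F statistic. The comparisons were each and both SETD2 hairpins against the control hairpin before and after OSKM, OSKM in control cells, the difference between the knockdown effects after and before OSKM, and the hairpins against each other. The value for both hairpins is the mean of their log2 fold changes. CPM were computed with the TMM factors and SDs are between libraries.

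Gene lists (26, of which 24 had at least 5 tested genes) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, on log2 CPM with a prior count of 2. The list of the 4 reprogramming factors was too short for a list test, and no mitochondrially encoded gene was among the genes tested. The lists, the comparisons, the tests, the rule for named genes and most alternatives were chosen before the data were examined. Named genes were SETD2, the delivered factors, NANOG, CDH1 and the H3K36 genes; the 6 highest and 6 lowest genes per comparison at an adjusted p under 0.05, at least 2-fold and at least 5 CPM on average, without overlap between the sides except for the difference of effects; and up to 4 members per list past the test. Genes of X inactivation and of the Y chromosome were not named. Where a group held 0 counts the fold was given against a floor of 3 counts, and for 1 to 3 counts with a 95% counting interval.

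The alternatives were scaling by library size only, DESeq2 1.42.0, limma-voom, a replicate block, only the groups compared, both hairpins as 1 group, each library left out in turn, and for lists an estimated correlation and fry. Added after the data were seen were fits without the 3 libraries with over 10% of their counts on a pair of unnamed IDs, and fits without these IDs. The fit without the 3 libraries left post-OSKM shSETD2-3 with 1 library, as leaving out a pre-OSKM SETD2 hairpin library did for its group. The spread for such a group came from the other groups. The gene test was tested on simulated data with known changes, set only in genes of at least 5 CPM on average. Of 67 such genes with 2-fold changes, 100% were recovered before OSKM, 98.5% after it and 95.5% for the difference of effects. For 1.5-fold changes these shares were 94.0%, 91.0% and 79.1%. False calls were 3.94%, 3.52% and 4.21% of calls. For OSKM in control cells 100% of 2-fold and 85.1% of 1.5-fold changes were recovered, and 5% of calls were false. The simulated counts were drawn gene by gene from the spread fitted to these data. Shifts shared by many genes of a library were not simulated, so the shares of false calls do not cover them. Recovery in genes of fewer counts was not measured. Libraries were also regrouped in other ways, and the calls of these groupings were counted beside those of the real one. Exon usage, splicing and reads were not analysed here, and some genes that met the rule for named genes are not reported here.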

Results

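RNA was sequenced from dH1f cells, fibroblasts that had been differentiated from the human embryonic stem cell line H1. The cells carried a control hairpin (shCntrl) or 1 of 2 hairpins, shSETD2-1 and shSETD2-3, against SETD2, the enzyme that trimethylates lysine 36 of histone H3 on transcribed genes. They were taken before (pre-OSKM) or 6 days after (post-OSKM) infection with viruses carrying POU5F1, SOX2, KLF4 and MYC, the factors that turn somatic cells into induced pluripotent stem cells. Of the 16 libraries, 3 were pre-OSKM controls, 2 belonged to each pre-OSKM SETD2 hairpin, and 3 belonged to each of the 3 post-OSKM groups. Each library held 21764800 to 32510600 counts, and 18302 genes were tested. A pair of IDs without a gene name took 0.461% to 1.49% of the counts in the pre-OSKM controls and 2.26% to 7.81% in the pre-OSKM knockdown libraries. After OSKM they took 2.18% to 3.59% in the controls and 1.08% to 18.2% in the knockdown libraries, where shSETD2-1 replicate 2 held 18.2%, shSETD2-3 replicate 2 held 17.3% and shSETD2-3 replicate 3 held 10.2%. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples. Intervals and floors cover counting error only.

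SETD2 itself was lower in each of the 10 libraries with a SETD2 hairpin than in any control library of the same time. Before OSKM it stood at 105 ± 0.458 CPM (SD, n = 3) with the control hairpin, 37.5 ± 0.331 (n = 2) with shSETD2-1 and 32.2 ± 0.59 (n = 2) with shSETD2-3. After OSKM the levels were 87.2 ± 3.71, 31.1 ± 1.66 and 26.4 ± 1.05 CPM (n = 3 each). With both hairpins the log2 fold change was -1.59 (SE 0.0589, adjusted p = 5.92e-32) before and -1.60 (SE 0.0538, adjusted p = 2.2e-34) after OSKM, or 0.331 and 0.329 of the control level. The difference in SETD2 between the hairpins (log2 0.22, shSETD2-1 higher) did not pass the test before OSKM (adjusted p = 0.0933) and did after it (log2 0.24, adjusted p = 0.0153).

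**Figure D1:**
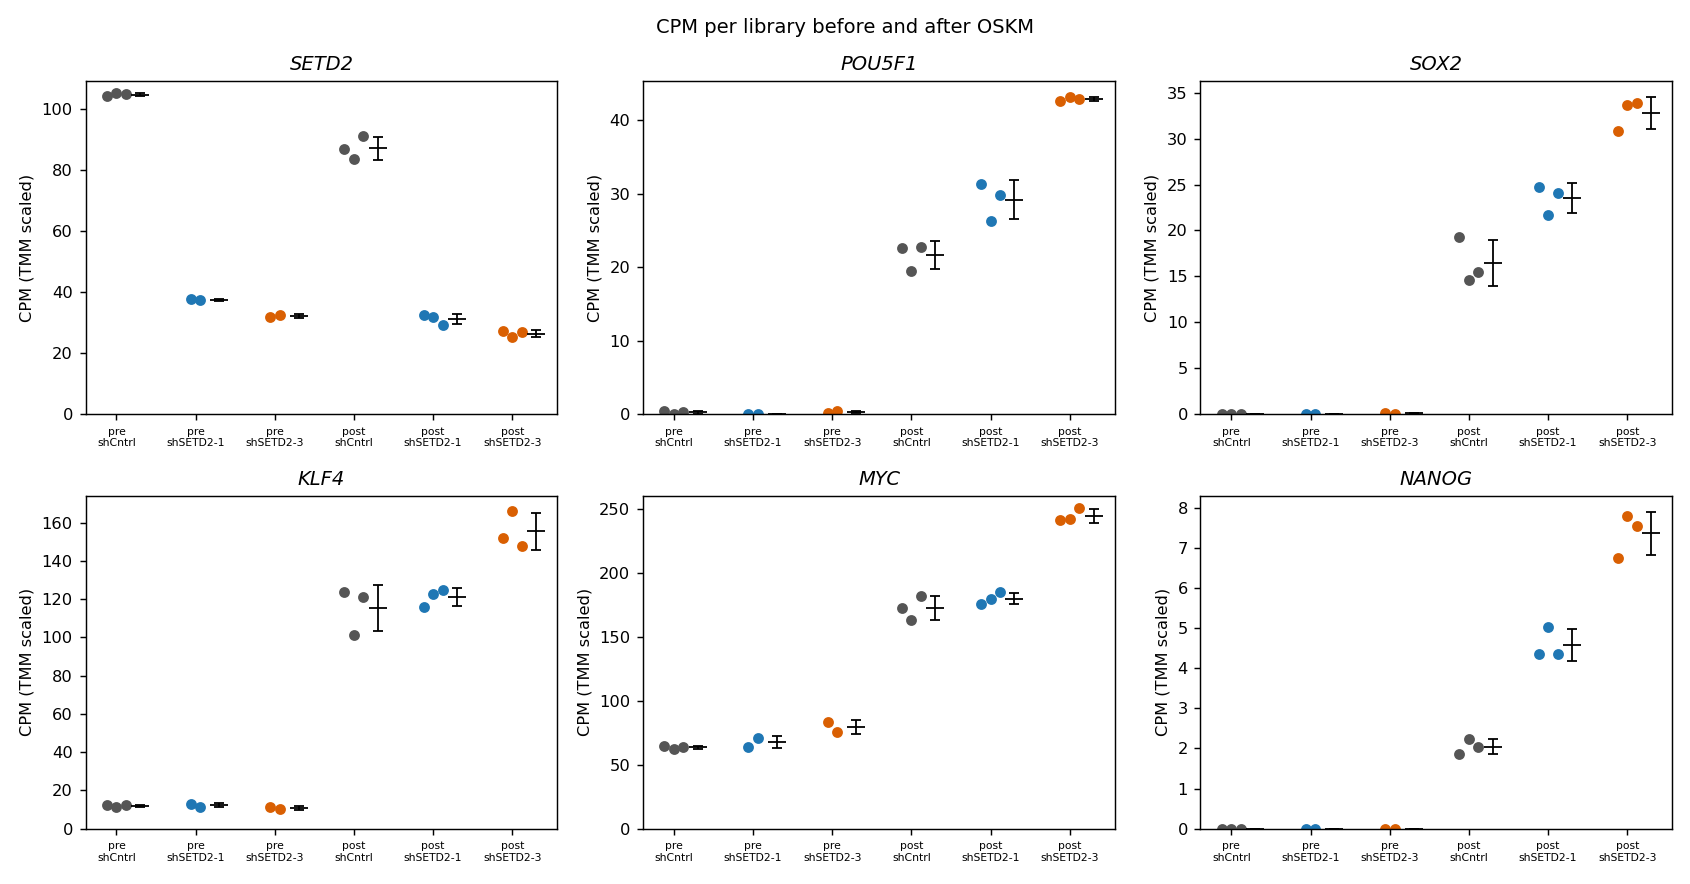
CPM of SETD2, the 4 delivered factors and NANOG in each of the 16 libraries (points), by hairpin and time, with the group mean and SD (black bars); axes start at 0 and differ between panels. SETD2 fell from 105 to 37.5 and 32.2 CPM before OSKM, and POU5F1 after OSKM stood at 21.6 CPM with the control hairpin, 29.2 with shSETD2-1 and 42.9 with shSETD2-3.

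The first comparison asked what lower SETD2 did to fibroblasts before any reprogramming factor was added. Among genes of at least 5 CPM on average, NPTX1, a secreted neuronal pentraxin, fell furthest, from 17.3 ± 0.223 CPM (SD, n = 3) in controls to 2.08 ± 0.464 and 2.47 ± 0.189 (n = 2 each), a log2 fold change of -2.94 (SE 0.109, adjusted p = 5.92e-32). The orphan nuclear receptor NR4A3 (log2 -1.99), the integrin subunit ITGA8 (-1.62), the prostaglandin E2 receptor PTGER2 (-1.62) and the cytokine signalling inhibitor SOCS2 (-1.62) also fell. Each was lower in all 4 knockdown libraries than in all 3 controls, as the rule for the lowest genes required. ARL6IP1, an endoplasmic reticulum membrane protein, rose furthest among genes of at least 5 CPM, from 33.5 ± 2.85 to 140 ± 2.75 and 147 ± 0.952 CPM (log2 2.10, SE 0.101, adjusted p = 9.06e-10). The mitochondrial carrier UCP2 (1.76), BRI3BP (1.41), LRRC15 (1.26) and the chloride transporter CLCN5 (1.19) rose as well. Each was higher in all 4 knockdown libraries than in all 3 controls, as the rule for the highest genes required.

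Amino acid and endoplasmic reticulum stress genes rose with the knockdown: of 27 integrated stress and unfolded protein response genes, 12 rose and 0 fell (14 and 0 adjusted over the list alone). They included the amino acid transporter SLC7A5 (log2 0.48), DDIT4 (0.57) and the pseudokinase TRIB3 (0.36), and the list passed camera at adjusted p = 3.06e-06 (adjusted p = 0.116 with an estimated correlation). By hairpin 16 rose with shSETD2-1 (list adjusted p = 1.71e-09, adjusted p = 0.0574 with an estimated correlation) and 6 with shSETD2-3, where the list did not pass (0.0972). The difference between the hairpins had an adjusted p = 4.19e-06 for this list (adjusted p = 0.169 with an estimated correlation). Of 24 cholesterol synthesis genes 9 rose and 0 fell (10 and 0 adjusted over the list alone), among them SC5D (0.36) and INSIG1 (0.34), with adjusted p = 0.000112 for the list (adjusted p = 0.13 with an estimated correlation). With shSETD2-1 10 were higher and 0 lower (adjusted p = 4.91e-08, adjusted p = 0.0574 with an estimated correlation), and with shSETD2-3 3 were higher and 2 lower (0.299). Between the hairpins the list had an adjusted p = 3.64e-05 (adjusted p = 0.169 with an estimated correlation). Glycolysis and hypoxia genes gave 12 of 29 higher and 1 lower (12 and 2 adjusted over the list alone), with hexokinase HK2 (0.42) and the glucose transporter SLC2A1 (0.34) among those that rose. The list had an adjusted p = 0.00109, and an adjusted p = 0.382 with an estimated correlation. It passed with shSETD2-3 (13 higher, 1 lower, adjusted p = 3.54e-06, adjusted p = 0.26 with an estimated correlation) and not with shSETD2-1 (8 higher, 1 lower, 0.314), where the median was 0.03 and the mean -0.07. The hairpins differed in it at adjusted p = 0.0021 (adjusted p = 0.473 with an estimated correlation). Replication-dependent histone genes, near-identical copies whose single values are uncertain, gave 4 of 14 higher (6 adjusted over the list alone), as in H2BC12 (0.33). For this list camera gave an adjusted p = 0.00051, and an adjusted p = 0.116 with an estimated correlation. In the interferon response list the median was 0.84 above control, yet only 2 of 30 genes passed (1 adjusted over the list alone). The list passed camera at adjusted p = 1.59e-05 (adjusted p = 0.561 with an estimated correlation). The genes that passed were 2 lower and 0 higher without shSETD2-1 replicate 1, and 0 without control replicate 2 or 3 or shSETD2-3 replicate 3. Without post-OSKM control replicate 1 they were 5 higher.

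Among 27 writers, erasers and readers of H3K36 methylation, 6 fell before OSKM and 0 rose (the same adjusted over the list alone). Beside SETD2 itself they included the DNA methyltransferase DNMT3B (log2 -0.61, SE 0.145, adjusted p = 0.00177), which binds methylated H3K36, and the actin histidine methyltransferase SETD3 (-0.30). The list passed at adjusted p = 0.0178 (adjusted p = 0.116 with an estimated correlation), with shSETD2-1 alone at 0.0222 (adjusted p = 0.116 with an estimated correlation) and with shSETD2-3 alone at 0.0621. The difference between the hairpins did not pass (0.909). SETD2, the hairpins' own target, is a member of this list, which was not tested without it. Of 25 Wnt pathway genes 5 fell and 1 rose (7 and 1 adjusted over the list alone), with the secreted antagonists SFRP1 (-0.79) and DKK3 (-0.30) lower and the receptor FZD2 (0.38) higher. As a list these genes had an adjusted p = 0.0239, and an adjusted p = 0.13 with an estimated correlation; the list did not pass without the pre-OSKM shSETD2-1 library of replicate 1 (adjusted p = 0.095) or without the 3 libraries high in the unnamed IDs (0.0516). By hairpin it passed with shSETD2-3 (0.0299, adjusted p = 0.26 with an estimated correlation) and not with shSETD2-1 (0.183), and the difference between them did not pass (0.608). G2 and M phase genes gave 6 of 30 higher and 1 lower (7 and 1 adjusted over the list alone), ECT2 (0.52) the furthest. Camera put this list at an adjusted p = 0.0321, and an adjusted p = 0.653 with an estimated correlation. With shSETD2-3 10 were higher and 0 lower (adjusted p = 3.54e-06, adjusted p = 0.446 with an estimated correlation), and with shSETD2-1 1 was higher and 2 lower with the opposite direction (0.569). The hairpins differed in this list at adjusted p = 1.61e-07 (adjusted p = 0.395 with an estimated correlation). The list of both hairpins did not pass without control replicate 1 (adjusted p = 0.324), shSETD2-1 replicate 3 (0.126) or shSETD2-3 replicate 3 (0.213), or with a replicate block (0.0588). Collagens and extracellular matrix genes went both ways, 7 of 34 higher and 13 lower (11 and 15 adjusted over the list alone; list adjusted p = 0.266), with MFAP4 (0.83) and FBLN5 (0.77) higher and the basement membrane collagen COL4A1 (-0.40) lower. By hairpin the list was lower with shSETD2-3 (5 higher, 16 lower, adjusted p = 0.00684, adjusted p = 0.452 with an estimated correlation) and did not pass with shSETD2-1 (10 higher, 14 lower, 0.966). Their difference had an adjusted p = 0.0284 (adjusted p = 0.598 with an estimated correlation). Both directions also occurred in TGF-beta targets and contractile genes (8 of 24 higher, 8 lower; list adjusted p = 0.928), mesenchymal genes (6 of 29 higher, 9 lower; 0.604) and epithelial genes (4 of 24 higher, 4 lower; 0.639).

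The other lists did not pass before OSKM. Pluripotency genes were barely counted at that time (0 of 21 higher, 1 lower; list adjusted p = 0.0896), and S phase genes gave 1 of 27 higher and 3 lower (0.0535). With shSETD2-1 the S phase list passed (1 higher, 6 lower, adjusted p = 0.00521, adjusted p = 0.465 with an estimated correlation), and with shSETD2-3 it did not (1 higher, 0 lower, 0.907). Between the hairpins it had an adjusted p = 0.0021 (adjusted p = 0.473 with an estimated correlation). With both hairpins it did pass without control replicate 1 (adjusted p = 0.0098), shSETD2-1 replicate 3 (0.00315), shSETD2-3 replicate 3 (0.00239) or post-OSKM control replicate 3 (0.0467), with a replicate block (0.0281) and without the pair of unnamed IDs (0.0454). Without shSETD2-3 replicate 3 the pluripotency (0.0422) and DNA repair lists (0.0213) passed as well, and without control replicate 3 the AP-1 list (0.0252). AP-1 and immediate early genes gave 4 of 25 higher and 2 lower (0.0681), with IER3 (0.40) higher, and p53 targets 5 of 29 higher and 1 lower (0.314), with GADD45B (0.45) higher and ZMAT3 (-0.33) lower. DNA repair (0 of 29 higher, 1 lower; 0.197), inflammatory (2 of 27 higher, 3 lower; 0.714) and ribosomal protein genes (1 of 30 higher, 2 lower; 0.639) did not pass. Markers of endothelial cells (2 of 11 higher, 2 lower; 0.604) and muscle and cartilage (2 of 12 higher, 2 lower; 0.639) did not pass. Nor did those of nerve (1 of 8 higher, 1 lower; 0.639), endoderm and trophoblast (1 of 9 higher, 0 lower; 0.775) and blood (0 of 9; 0.928). Of the genes to be delivered later, KLF4 did not pass (log2 -0.05, adjusted p = 0.8) and MYC rose by 0.20 (SE 0.0489, adjusted p = 0.00267), a call lost with scaling by library size only (adjusted p = 0.423). The epithelial cadherin CDH1 was higher by log2 2.27 (SE 0.579, adjusted p = 0.00417), but not without control replicate 3 (log2 1.75, adjusted p = 0.0507) or by limma-voom (adjusted p = 0.0925).

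In all, 925 genes were higher and 1031 lower before OSKM at an adjusted p under 0.05 by edgeR's quasi-likelihood test, and 63 and 113 of them changed at least 2-fold. With TMM and without the pair of unnamed IDs, which totals by library size include, 870 were higher and 1076 lower. Without scaling beyond library size the split was 329 higher and 888 lower, and the median of all genes moved by under 0.1 on the log2 scale. With both hairpins fitted as 1 group 845 genes passed, and DNMT3B, SFRP1, MYC and CDH1 were among the named genes that did not. Under scaling by library size only the genes that rose numbered 3 rather than 12 in the stress response list, 2 rather than 12 in glycolysis and hypoxia, 3 rather than 9 in cholesterol synthesis, 1 rather than 6 in G2 and M phase, 1 rather than 5 among p53 targets and 0 rather than 4 among histones. In the lists that went both ways it left 2 higher and 12 lower matrix genes (7 and 13 above), 2 and 7 TGF-beta targets (8 and 8), 2 and 6 mesenchymal genes (6 and 9) and 3 and 3 epithelial genes (4 and 4).

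OSKM in cells with the control hairpin gave the background against which the knockdown was read. No group was infected without the factors or kept as long in culture without infection. Changes given here for OSKM therefore cannot be told apart from those of infection or of time in culture. POU5F1 rose from 0.216 ± 0.19 to 21.6 ± 1.89 CPM (SD, n = 3 each), KLF4 from 11.9 ± 0.654 to 116 ± 12.2 and MYC from 63.7 ± 1.1 to 173 ± 9.36. SOX2, at 0 counts before, was at least 481-fold higher against a floor of 3 counts over the group. Counts per gene cannot separate the delivered from the cells' own copies of these 4 genes. NANOG, a pluripotency factor that was not delivered, was at least 60.1-fold higher, at 2.05 ± 0.184 CPM. The keratin genes KRT14 and KRT6A rose, KRT14 from 0.177 ± 0.185 to 409 ± 37.2 CPM, KRT6A from 0.0561 ± 0.0972 to 150 ± 10.4 CPM. Reads shared with near-identical keratins make these values uncertain. The secreted protein PI16 rose from 0.16 ± 0.0509 to 128 ± 5.26. The scavenger receptor SCARA5 was at least 1060-fold higher, and the protease KLK10, with 3 counts before, rose by a ratio of 755 (95% counting interval 258 to 3663). The BMP antagonist GREM1 fell from 3681 ± 152 to 925 ± 161 CPM (log2 -1.99). The genes PTPRN (-2.58), the sarcomere protein MYPN (-2.44), the prostaglandin synthase PTGS2 (-2.38), TENM2 (-1.99) and GDF6 (-1.96) fell with it. The 3 libraries of each side did not overlap, as the rule for the lowest genes required.

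Cell cycle genes fell as a group after OSKM in control cells: all 30 G2 and M phase genes (the same adjusted over the list alone), with CENPF (log2 -1.27) and KIF20A (-1.18) among the furthest (adjusted p = 2.73e-27). So did 25 of 27 S phase genes (26 adjusted over the list alone), with both ribonucleotide reductase subunits RRM1 (-0.95) and RRM2 (-0.82) lower (adjusted p = 2.13e-12). DNA repair and checkpoint genes gave 20 of 29 lower and 0 higher (22 and 0 adjusted over the list alone; adjusted p = 1.01e-09), among them FANCA (-1.12) and BRCA1 (-0.85). H3K36 genes gave 12 of 27 lower and 2 higher (13 and 2 adjusted over the list alone; adjusted p = 0.00788), led by the dimethyltransferase NSD2 (-1.11), with SETD2 at -0.27 (adjusted p = 0.00031). In the pluripotency list, which holds 2 of the delivered factors, 18 of 21 genes rose and 1 fell (20 and 1 adjusted over the list alone; adjusted p = 6.8e-14). The median log2 fold change of 6.00 became 3.94 with the 10 members at or under the floor set to their bound. Markers of other cell types rose too: 8 of 11 endothelial genes, as in the angiopoietin receptor TEK (3.06) (adjusted p = 4.2e-05), and 9 of 12 muscle and cartilage genes, as in TNNT1 (3.38) and SOX9 (2.03) (adjusted p = 2.62e-05). So did 13 of 24 epithelial genes, as in KRT18 (1.23) (adjusted p = 0.000563), and 4 of 8 neural genes, as in MAP2 (1.66) (adjusted p = 0.0113). Adjusted over the list alone these counts were 8, 10, 14 and 4. These 9 lists were the ones that also passed with an estimated correlation.

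The interferon response list rose in 27 of 30 genes after OSKM in control cells (27 adjusted over the list alone), with IFI27 at log2 3.59 and MX1 at 4.18. Its level differed widely between the 3 post-OSKM control libraries, at a mean log2 CPM of 4.88, 3.79 and 3.21. Tested together they gave an adjusted p = 3.81e-10, and an adjusted p = 0.217 with an estimated correlation. Cholesterol synthesis genes gave 12 of 24 higher and 1 lower (12 and 1 adjusted over the list alone), as in the isoprenoid isomerase IDI1 (0.42). The group as a whole had an adjusted p = 0.000888, and an adjusted p = 0.124 with an estimated correlation. Glycolysis and hypoxia genes gave 16 of 29 lower and 3 higher (17 and 3 adjusted over the list alone), with enolase ENO2 (-1.09) and BNIP3 (-0.93) lower. The list had an adjusted p = 9.83e-05, and an adjusted p = 0.181 with an estimated correlation. Ribosomal protein genes rose slightly in 17 of 30 (18 adjusted over the list alone; list median 0.13; adjusted p = 0.00376; adjusted p = 0.479 with an estimated correlation), and histone genes in 6 of 14 (6 adjusted over the list alone; adjusted p = 0.00913; adjusted p = 0.124 with an estimated correlation). Matrix genes gave 19 of 34 higher and 9 lower (20 and 9 adjusted over the list alone), the proteoglycans DCN (1.94) and LUM (1.86) and FBLN2 (2.57) higher and elastin ELN (-1.87) lower. For this list camera gave an adjusted p = 0.0335, and an adjusted p = 0.358 with an estimated correlation. Without replicate 2 of the pre-OSKM or the post-OSKM controls this list did not pass (adjusted p = 0.0647 and 0.0753). The p53 target and kinase inhibitor list did not pass (adjusted p = 0.223), while 12 of its 29 genes rose and 7 fell, with BTG2 (3.00) and CDKN1A (0.74) higher. Nor did the mesenchymal (10 of 29 higher, 13 lower; 0.196), TGF-beta (8 of 24 higher, 11 lower; 0.483), inflammatory (6 of 27 higher, 11 lower; 0.209) and AP-1 lists (12 of 25 higher, 7 lower, 0.282). The same held for the stress response (10 of 27 higher, 5 lower; 0.441), Wnt (12 of 25 higher, 5 lower; 0.209), blood (1 of 9 higher; 0.256) and endoderm and trophoblast lists (4 of 9 higher, 1 lower; 0.209). The mesenchymal marker S100A4 (2.36) and smooth muscle actin ACTA2 (1.04) rose among them, and N-cadherin CDH2 (-1.07) and the collagenase MMP1 (-1.91) fell. Across all genes 3189 were higher and 2720 lower, of which 1263 and 314 changed at least 2-fold; with scaling by library size only, 2 ribosomal protein genes passed in place of 17, and 8 cholesterol genes (12), 15 matrix genes (19) and 7 stress response genes (10) rose.

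After OSKM, pluripotency genes were higher in the knockdown cells than in the controls at the same day. The Nodal antagonist LEFTY2 stood at 3.17 ± 0.62 CPM with the control hairpin, 27.0 ± 3.16 with shSETD2-1 and 35.0 ± 6.7 with shSETD2-3 (SD, n = 3 each), a log2 fold change of 3.27 (SE 0.148, adjusted p = 1.07e-24). NANOG rose from 2.05 ± 0.184 to 4.58 ± 0.391 and 7.36 ± 0.545 CPM (2.83-fold, SE of log2 0.248, adjusted p = 2.11e-06), and L1TD1 (1.47) and SALL4 (1.24) rose as well. Of 21 pluripotency genes 14 rose and 0 fell (15 and 0 adjusted over the list alone; adjusted p = 1.62e-08, adjusted p = 0.00551 with an estimated correlation). Counts of all 4 factor genes were also higher, with delivered and own copies together. SOX2 rose by log2 0.75 (SE 0.109), POU5F1 by 0.71 (SE 0.111), MYC by 0.28 (SE 0.0429) and KLF4 by 0.25 (SE 0.0539). The rise of POU5F1 was 0.43 with shSETD2-1 and 0.99 with shSETD2-3, and KLF4 and MYC passed the test with shSETD2-3 only. The difference between the hairpins passed for all 4 factors (POU5F1 adjusted p = 0.00145, SOX2 0.00409, KLF4 1.82e-05, MYC 1.84e-10). Without POU5F1 and SOX2 the other 19 list genes kept a median of 0.94, with 17 of 19 above control. CDH1 rose too (2.82-fold, SE of log2 0.362, adjusted p = 0.00103). With both hairpins as 1 group MYC (adjusted p = 0.134) and KLF4 (0.111) did not pass, and KLF4 did not pass with scaling by library size only (0.133).

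Among other genes with the knockdown after OSKM, ARL6IP1 rose from 26.4 ± 5.67 to 116 ± 2.95 and 104 ± 3.5 CPM (SD, n = 3 each; log2 2.05, SE 0.0986). So did the guanylate cyclase subunit GUCY1A1 (1.91), the retinal reductase DHRS3 (1.86) and MFAP3L (1.83). The smooth muscle myosin MYH11 fell from 70.0 ± 3.64 to 16.4 ± 1.88 and 9 ± 0.421 CPM (log2 -2.53, SE 0.0851, adjusted p = 2.31e-34). The genes NR4A3 (-2.71), the ephrin receptor EPHA5 (-2.36), the cartilage proteoglycan ACAN (-1.82), MRGPRF (-1.74) and the RANKL decoy TNFRSF11B (-1.66) fell with it. Each of these 10 genes was on one side of all 3 controls in all 6 knockdown libraries, as the rule for the highest and lowest genes required.

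The integrated stress and unfolded protein response list was higher again: 19 of 27 genes rose and 0 fell (21 and 1 adjusted over the list alone), with DDIT4 (log2 0.80), the lipoprotein receptor VLDLR (0.66), SESN2 (0.59) and CHAC1 (0.47) furthest. As a list these genes had an adjusted p = 4.7e-12, and an adjusted p = 0.0254 with an estimated correlation. Glycolysis and hypoxia genes gave 19 of 29 higher and 1 lower (20 and 1 adjusted over the list alone), with the prolyl hydroxylase P4HA1 (0.70) and SLC2A1 (0.64) higher and adrenomedullin ADM (-1.12) lower. Camera put this list at an adjusted p = 1.16e-10, and an adjusted p = 0.0488 with an estimated correlation. Of 29 p53 targets and kinase inhibitors 12 rose and 2 fell (13 and 3 adjusted over the list alone), the cell cycle inhibitor CDKN2B rising from 63.8 ± 2.03 to 140 ± 5.22 and 163 ± 5.3 CPM and the death receptor FAS (-0.82) falling. Tested together they gave an adjusted p = 0.00365, and an adjusted p = 0.0302 with an estimated correlation. Epithelial genes gave 9 of 24 higher and 5 lower (10 and 6 adjusted over the list alone), with the desmosome genes DSG2 (1.03) and DSP (0.56) and the simple epithelial keratins KRT18 (0.57) and KRT8 (0.45) higher. The group as a whole had an adjusted p = 0.0111, and an adjusted p = 0.0488 with an estimated correlation. It passed with shSETD2-3 (adjusted p = 0.00264, adjusted p = 0.0335 with an estimated correlation) and not with shSETD2-1 (0.212), and the hairpins differed at adjusted p = 0.0104 (adjusted p = 0.0897 with an estimated correlation). Of markers of other cell types, 4 of 8 neural genes rose, as in STMN2 (1.37). Of the endothelial genes 5 of 11 rose and 2 fell, as in EMCN (1.43), TEK (0.71) and EGFL7 (-0.77), the same counts adjusted over the list alone (adjusted p = 0.0111 for each list, and for each adjusted p = 0.0488 with an estimated correlation). Ribosomal protein genes gave 20 of 30 higher and 0 lower (24 and 0 adjusted over the list alone), by a list median of 0.17, with RPS12 (0.36) furthest. With scaling by library size only 1 of the 30 passed, and reads from their processed pseudogenes make single values uncertain. The list had an adjusted p = 1.62e-08, and an adjusted p = 0.347 with an estimated correlation. G2 and M phase genes gave 7 of 30 higher and 1 lower (9 and 1 adjusted over the list alone), as in ECT2 (0.37) and CDK1 (0.36). For this list camera gave an adjusted p = 0.00677, and an adjusted p = 0.491 with an estimated correlation. With shSETD2-1 16 were higher and 1 lower (adjusted p = 6.31e-07, adjusted p = 0.286 with an estimated correlation), and with shSETD2-3 2 were higher and 2 lower (0.89). Between the hairpins this list had an adjusted p = 2.77e-08 (adjusted p = 0.341 with an estimated correlation).

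Matrix genes were lower with the knockdown after OSKM: 19 of 34 fell and 8 rose (19 and 9 adjusted over the list alone), with FBLN1 (log2 -0.71), thrombospondin THBS2 (-0.61), fibrillin FBN2 (-0.60) and DCN (-0.57) lower. As a list these genes had an adjusted p = 0.00277, and an adjusted p = 0.347 with an estimated correlation. Of 25 Wnt pathway genes 10 fell and 4 rose, the same adjusted over the list alone, with SFRP1 from 314 ± 17.5 to 139 ± 7.28 and 83.5 ± 1.54 CPM. Camera put this list at an adjusted p = 0.0462, and an adjusted p = 0.155 with an estimated correlation. By hairpin it passed with shSETD2-3 (0.047, adjusted p = 0.157 with an estimated correlation) and not with shSETD2-1 (0.194), and the difference between them did not pass (0.323). It did not pass without pre-OSKM control replicate 1 (adjusted p = 0.0515), or without the post-OSKM libraries control replicate 1 (0.0549), shSETD2-1 replicate 2 (0.0691) or 3 (0.0738), or shSETD2-3 replicate 1 (0.0558) or 2 (0.0595). In the interferon list 5 of 30 genes fell and 0 rose (3 and 0 adjusted over the list alone), the guanylate-binding protein gene GBP1 (-0.24) among them. Tested together they gave an adjusted p = 0.0473, and an adjusted p = 0.647 with an estimated correlation. With shSETD2-3 11 were lower (median -1.05, adjusted p = 6.24e-05, adjusted p = 0.448 with an estimated correlation, and 0.0575 by fry). With shSETD2-1 0 genes passed, the median was -0.08 and camera's direction was upward (0.663). The hairpins differed in this list at adjusted p = 2.77e-08 (adjusted p = 0.362 with an estimated correlation). Without post-OSKM control replicate 1, the library with a mean log2 CPM of 4.88 for this list, the direction turned and the list did not pass (adjusted p = 0.705). Nor did it pass without pre-OSKM control replicate 1 (0.0515) or 3 (0.0506), or without post-OSKM shSETD2-1 replicate 1 (0.0635) or 3 (0.188) or shSETD2-3 replicate 1 (0.0845) or 3 (0.0597). Without post-OSKM control replicate 3 12 genes were lower, and without control replicate 1 2 were lower and 2 higher. Mesenchymal genes went both ways, 6 of 29 higher and 12 lower (list adjusted p = 0.16), with the fibroblast activation protease FAP (0.91) higher and the growth factor receptor PDGFRA (-0.63) lower. So did TGF-beta targets and contractile genes (9 of 24 higher, 10 lower, 0.377), as in the feedback inhibitors PMEPA1 (1.40) and SKIL (0.70) against LMOD1 (-1.02) and smooth muscle actin ACTG2 (-0.75). Inflammatory and secretory genes likewise split (6 of 27 higher, 7 lower; 0.452), as in CCL2 (0.89) against MMP1 (-0.93), ICAM1 (-0.81) and CXCL12 (-0.79). With shSETD2-1 that list was lower (3 higher, 7 lower, adjusted p = 0.0489, adjusted p = 0.112 with an estimated correlation), and with shSETD2-3 it did not pass (0.764). The hairpins differed in it at adjusted p = 0.000247 (adjusted p = 0.0256 with an estimated correlation). H3K36 genes gave 6 of 27 higher and 6 lower (list adjusted p = 0.634) and AP-1 and immediate early genes 9 of 25 higher and 5 lower (0.178). Not past the test were also cholesterol synthesis (6 of 24 higher, 1 lower; 0.377), S phase (2 of 27 higher, 3 lower; 0.728) and DNA repair (2 of 29 higher, 1 lower, 0.73). The cholesterol list passed with shSETD2-1 (7 higher, 1 lower, adjusted p = 0.019, adjusted p = 0.286 with an estimated correlation) and not with shSETD2-3 (0.592), and between the hairpins it had an adjusted p = 8.16e-05 (adjusted p = 0.141 with an estimated correlation). Nor did histones pass (2 of 14 higher, 1 lower; 0.178), muscle and cartilage (6 of 12 higher, 2 lower; 0.594), endoderm and trophoblast (1 of 9 higher, 1 lower; 0.238) or blood (0 of 9; 0.901).

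**Figure D2:**
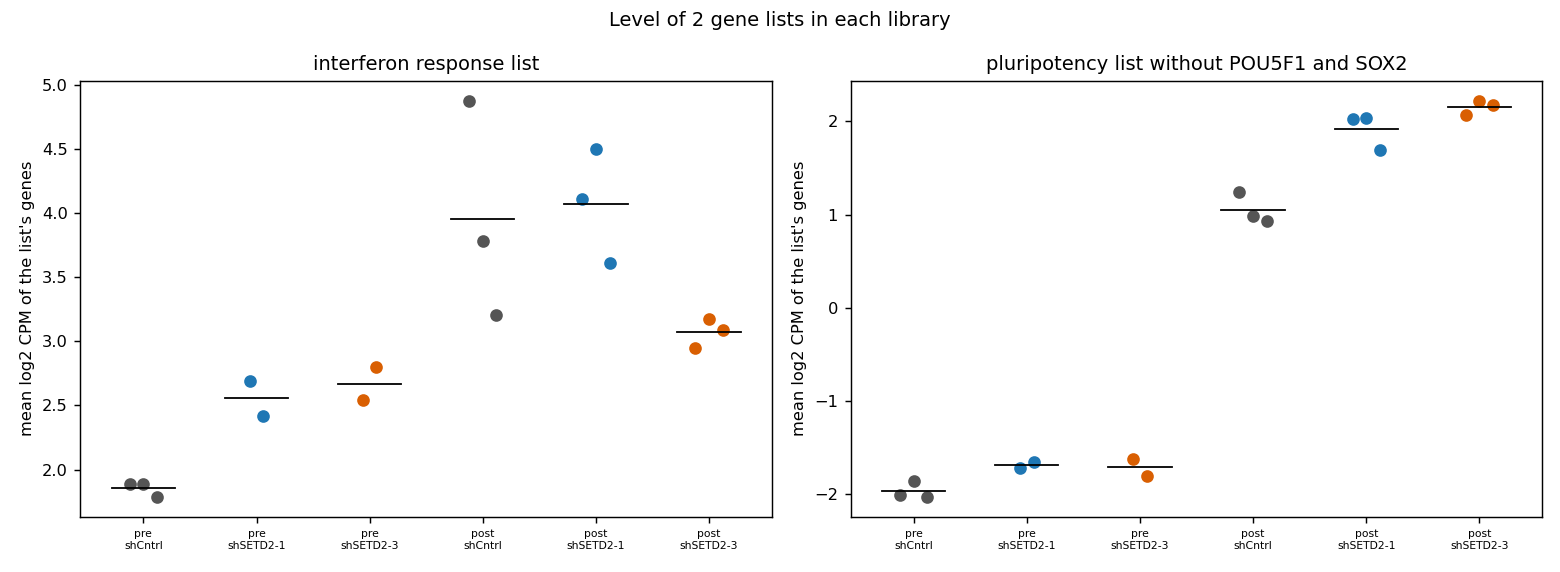
Mean log2 CPM of the interferon response list and of the pluripotency list without POU5F1 and SOX2 in each of the 16 libraries, by hairpin and time, with the group mean (bars). The interferon list stood at 4.88, 3.79 and 3.21 in the post-OSKM controls, and the pluripotency list at 1.24, 0.98 and 0.93 in them against 1.69 to 2.22 in the post-OSKM knockdown libraries.

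**Figure D3:**
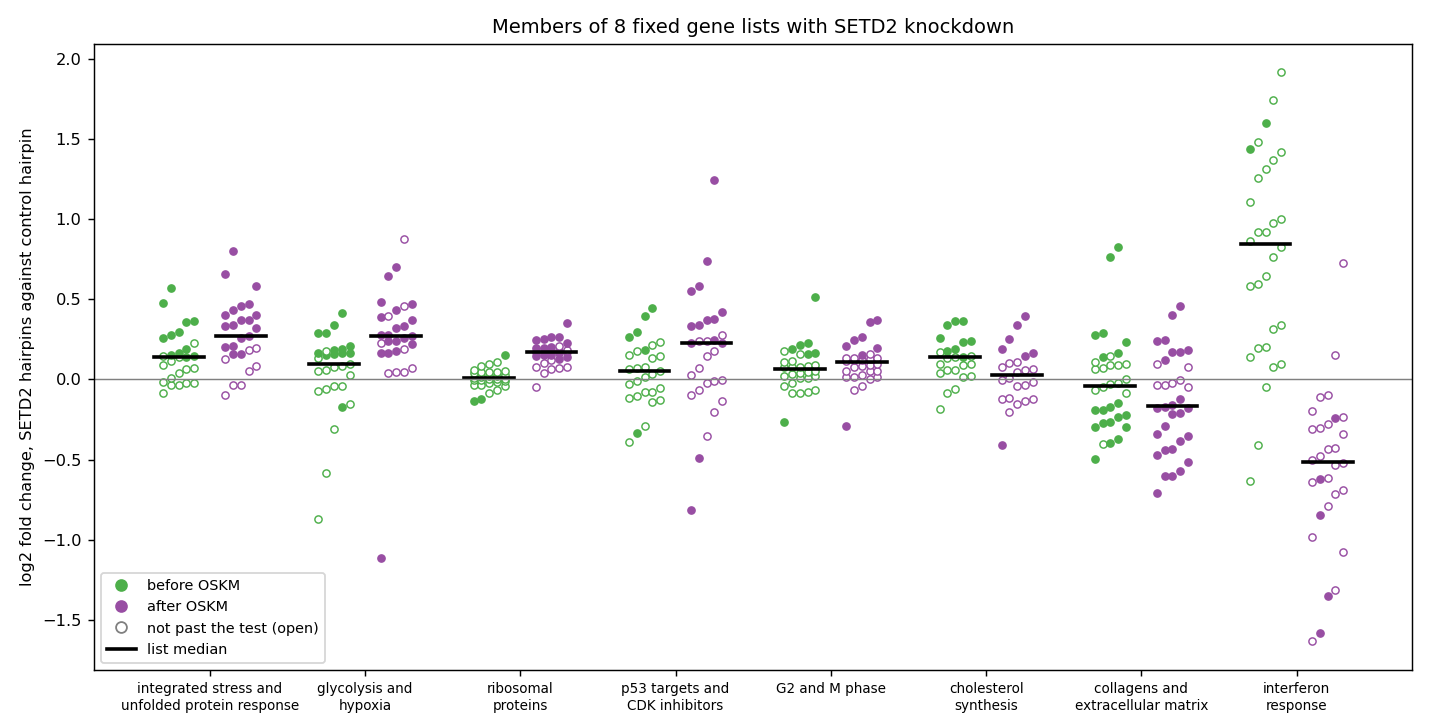
Log2 fold change of each tested member of 8 fixed gene lists, SETD2 hairpins against the control hairpin, before OSKM (green) and after OSKM (purple); filled points passed an adjusted p of 0.05, open points did not, and black lines are list medians. The stress response list had a median of 0.14 before and 0.27 after OSKM, and the interferon list 0.84 and -0.51. With scaling by library size only the medians of the p53 list before OSKM and of the cholesterol list after it turned from above 0 to -0.01 and -0.04.

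After OSKM 1930 genes were higher and 2240 lower with the knockdown by edgeR's quasi-likelihood test, and 248 and 258 of them changed at least 2-fold. With TMM and without the pair of unnamed IDs, which totals by library size include, 1927 were higher and 2232 lower. Without scaling beyond library size the split was 838 higher and 2442 lower, a shift of the median of all genes of under 0.1 on the log2 scale. Stress response genes that rose then numbered 12 rather than 19, and glycolysis and hypoxia genes 10 rather than 19. The genes that rose numbered 7 rather than 12 among p53 targets, 2 rather than 7 in G2 and M phase, 1 rather than 4 among neural markers, 2 rather than 6 in cholesterol synthesis, 1 rather than 6 in the H3K36 list and 2 rather than 8 among matrix genes. Those of the AP-1 list numbered 5 rather than 9, of the TGF-beta list 6 rather than 9 and of the mesenchymal list 3 rather than 6. With both hairpins as 1 group KRT18 (adjusted p = 0.0514), KRT8 (0.218) and DCN (0.0577) did not pass. Of the genes called at each time, 1301 were shared between the comparisons, and 1222 of these (93.9%) had the same direction. They comprised 690 lower and 532 higher genes at both times, where independent lists of these sizes would share 126 and 97.5; the libraries behind the comparisons did not overlap.

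Whether the knockdown acted differently before and after OSKM was tested as the difference of its effects. Of the genes named here the joint lubricant PRG4 had the furthest downward difference of log2 fold changes (-2.35), but it did not pass with both hairpins as 1 group (adjusted p = 0.495) or by limma-voom (0.0556). MYH11 stood at 70.0 CPM in post-OSKM controls against 16.4 and 9 in the knockdown groups (difference -1.95, SE 0.183). The matrix protein TNXB reached 334 ± 8.13 CPM after OSKM against 167 ± 4.5 and 186 ± 9.31 (SD, n = 3 each). Its difference (-1.64, SE 0.167) was larger than this fall, so it also held a rise with the knockdown before OSKM. TNFRSF11B gave -1.56. The pericyte gene RGS5 reached 57.8 ± 2.46 against 20.3 ± 1.32 and 17.5 ± 1.59 (-1.48, SE 0.147), and PAX8 gave -1.47. In the other direction NPTX1, which fell 7.67-fold before OSKM, was less far below control after it, at 73.8 ± 2.49 against 29.2 ± 2.77 and 38.6 ± 2.29 CPM (difference 1.80, SE 0.134). The granzyme B inhibitor SERPINB9 (1.71) and KIF26A (1.62) rose more after OSKM. DHRS3 (2.16) did not pass with both hairpins as 1 group, and ITGB4 (1.80) did not pass without pre-OSKM control replicate 1 (0.78, adjusted p = 0.587) or shSETD2-3 replicate 1 (0.0524).

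Of the lists, only the pluripotency genes passed this test with an estimated correlation as well. Of these, 2 of 21 genes, DNMT3B (0.76) and DPPA4 (0.65), passed singly (3 adjusted over the list alone). DNMT3B had fallen with the knockdown before OSKM, and its difference includes that fall. The list's difference was upward with adjusted p = 5.87e-07 (adjusted p = 0.0122 with an estimated correlation), with 12 members at or under the floor in at least 1 group. Ribosomal protein genes (10 of 30 higher; adjusted p = 4.91e-08), glycolysis and hypoxia genes (9 higher and 1 lower of 29; 1.2e-06) and stress response genes (9 of 27 higher; 3.62e-05) rose more after OSKM. Matrix genes (16 lower and 4 higher of 34; 0.000407) and the interferon list (2 of 30 lower; 4.43e-08) were lower relative to before it. Adjusted over the list alone the counts were 16 higher, 12 higher and 1 lower, 11 higher and 1 lower, 18 lower and 6 higher, and 3 lower. With an estimated correlation these 5 did not pass, at adjusted p = 0.323, 0.164, 0.164, 0.272 and 0.319. The interferon count depended on single libraries. Without post-OSKM control replicate 3 it was 10 lower. Without post-OSKM control replicate 1 it was 1 lower, and the list median moved from -1.28 to -0.58. Across the remaining lists H3K36 genes gave 2 of 27 higher (adjusted p = 0.0758) and endothelial genes 2 of 11 higher (0.0758). TGF-beta targets gave 4 of 24 higher and 9 lower (0.118), mesenchymal genes 2 of 29 higher and 7 lower (0.238) and Wnt genes 1 of 25 higher and 3 lower (0.65). Histones (0.102), DNA repair (0.118), endoderm and trophoblast (0.315), G2 and M phase (0.493), inflammatory (0.671), muscle and cartilage (0.692), AP-1 (0.864) and blood lists (0.864) did not pass. Without the 3 libraries high in the unnamed IDs the histone (0.0384) and G2 and M phase lists (0.0353) did. Without pre-OSKM shSETD2-3 replicate 3 the H3K36 (0.0424), DNA repair (0.0263), endothelial (0.0354) and histone lists (0.0464) passed. So did the endothelial list without pre-OSKM shSETD2-1 replicate 3 (0.0372) or post-OSKM control replicate 3 (0.0375), the TGF-beta list without post-OSKM control replicate 1 (0.0398) and the histone list without post-OSKM control replicate 2 (0.0321). Across all genes 519 differences were above 0 and 664 below it, 166 of them at least 2-fold. Scaling by library size only left 548 genes, with 0 of the ribosomal, 1 of the glycolysis, 1 of the stress response and 1 of the p53 genes rising. It gave 7 lower and 1 higher matrix genes, 7 lower interferon genes in place of 2, 1 lower and 2 higher TGF-beta targets and 1 lower and 1 higher mesenchymal genes. Both hairpins as 1 group left 342 genes, without DNMT3B (adjusted p = 0.211) and DPPA4 (0.112).

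A further 5 lists passed only narrowly, and none of them with an estimated correlation. Epithelial genes (6 higher and 1 lower of 24; adjusted p = 0.0223, adjusted p = 0.111 with an estimated correlation) included DSP (0.68) and DSG2 (0.59). The list did not pass without the pre-OSKM libraries control replicate 1 (0.0615) or shSETD2-1 replicate 1 (0.0522). Without the 3 libraries high in the unnamed IDs the epithelial (0.0519), cholesterol (0.135) and neural lists (0.105) did not pass. The p53 list (5 higher and 1 lower of 29; adjusted p = 0.0242, adjusted p = 0.111 with an estimated correlation), with CDKN2B (1.18), did not pass without pre-OSKM control replicate 1 (0.0513), shSETD2-1 replicate 1 (0.0522) or post-OSKM control replicate 1 (0.0522). Cholesterol genes (2 of 24 lower; adjusted p = 0.0242, adjusted p = 0.319 with an estimated correlation), with the cyclase LSS (-0.47), did not pass without pre-OSKM control replicate 3 (0.0992), shSETD2-1 replicate 1 (0.0522) or shSETD2-3 replicate 1 (0.111). Nor did they without post-OSKM control replicate 1 (0.0805) or shSETD2-1 replicate 2 (0.0535). S phase genes (2 higher and 1 lower of 27; adjusted p = 0.041, adjusted p = 0.447 with an estimated correlation) did not pass without pre-OSKM control replicate 3 (0.192), shSETD2-1 replicate 1 (0.155) or shSETD2-3 replicate 1 (0.29). Nor did they without post-OSKM control replicate 1 (0.0805), shSETD2-1 replicate 1 (0.0763) or 3 (0.062) or shSETD2-3 replicate 1 (0.0596). Neural genes (1 of 8 higher, NES at 0.50; adjusted p = 0.041, adjusted p = 0.164 with an estimated correlation) did not pass without pre-OSKM control replicate 1 (0.063) or 2 (0.0524), shSETD2-1 replicate 1 (0.067) or 3 (0.0518) or shSETD2-3 replicate 1 (0.0672). The same held for post-OSKM control replicate 2 (0.0993), shSETD2-1 replicate 1 (0.055), 2 (0.0578) or 3 (0.0539) and shSETD2-3 replicate 1 (0.0565) or 3 (0.0781).

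Lastly, the hairpins were compared with each other. Before OSKM shSETD2-1 gave 970 genes higher and 1041 lower and shSETD2-3 765 and 773; after it the counts were 1615 and 1933, and 1879 and 1986. Without scaling beyond library size the splits were 299 and 1128 for shSETD2-1 before OSKM, and after it 639 and 1900 for shSETD2-1 and 881 and 2040 for shSETD2-3. With shSETD2-3 before OSKM it was 305 and 429. Both hairpins called 346 genes higher and 339 lower before OSKM, where independent lists would share 40.5 and 44.0, and 1015 and 1131 after it, against 166 and 210; 33 and 41 genes were called in opposite directions. Across 10723 genes, which are not independent replicates, the covariance of the hairpins' log2 fold changes was 0.0367 before OSKM (r = 0.491) and 0.0743 after it (r = 0.745). Unchanged groups simulated against the same controls gave a covariance of 0.00779 and 0.00661 (r = 0.387 and 0.489) and at most 1 and 0 shared calls; the 3 controls are too few to split, so part of the excess may come from sharing them.

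The hairpins also differed directly, in 654 genes higher with shSETD2-1 and 645 lower before OSKM (167 and 442 with scaling by library size only), and 875 and 1015 after it (386 and 562). TYMS, the thymidylate synthase, fell with shSETD2-1 alone: 40.4 ± 3.21 CPM in pre-OSKM controls, 10.2 ± 0.411 with shSETD2-1 and 48.2 ± 3.34 with shSETD2-3, and after OSKM 24.3 ± 1.84, 8.47 ± 0.505 and 26.5 ± 2.1. The difference of shSETD2-1 minus shSETD2-3 was log2 -2.24 and -1.65 (SE 0.119 and 0.102, adjusted p = 7.68e-23 and 3.87e-20). For such a gene an average of the hairpins stands for neither hairpin alone.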

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

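Of the tests in this part, those of the factor level and of the interferon list were chosen only after results were seen, and the fit without 3 libraries was added after the data were seen. After OSKM the pluripotency list was higher with SETD2 knockdown (median 0.91 on the log2 scale). So were POU5F1 and SOX2, delivered and own copies counted together, more with shSETD2-3 than with shSETD2-1. If factor level set the list, its other 19 genes should be higher with shSETD2-3. Their median difference was 0.30 (12 of 19 above 0, range 0.22 to 0.36 with each library left out). The list did not pass camera in that contrast, with an unadjusted p of 0.0789, so whether factor level may account for the rise cannot be told. SETD2 itself was also lower with shSETD2-3 than with shSETD2-1 after OSKM, so the contrast cannot separate factor level from knockdown strength. Libraries with over 10% of counts on a pair of unnamed IDs did not account for it, since the list passed without all 3 of them (adjusted p = 2.34e-07).

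The interferon list was lower with knockdown after OSKM (adjusted p = 0.0473, and adjusted p = 0.647 with an estimated correlation) and higher before it. By hairpin the list had an adjusted p = 6.24e-05 with shSETD2-3 (median -1.05, adjusted p = 0.448 with an estimated correlation) and 0.663 with shSETD2-1 (median -0.08), and between the hairpins 2.77e-08 (adjusted p = 0.362 with an estimated correlation). A single post-OSKM control library could account for the fall of the hairpins' average: without control replicate 1 its direction turned (adjusted p = 0.705), while without control replicate 3 it was at adjusted p = 1.85e-05. For shSETD2-3 this stays open, since its libraries (mean log2 CPM 2.95 to 3.18) also lay below the other controls (3.79 and 3.21). The rise before OSKM passed at the preset correlation (adjusted p = 1.59e-05) and did not with an estimated one (adjusted p = 0.561 with an estimated correlation).

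More genes changed with knockdown after OSKM (4170) than before it (1956), where each hairpin group had 1 library fewer. With replicate 2 of both post-OSKM knockdown groups left out, 3872 genes still passed after OSKM against 1942 before, a ratio of 1.99, so library number was excluded as the explanation.

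Regrouping the libraries in other ways asked how often other groupings gave as many calls as the real one. Each grouping, the real one included, was fitted anew and not in the model of 6 groups. Comparisons of both hairpins with control, and the difference of effects, took both hairpins as 1 group. All but the difference of effects used only the libraries compared. The real counts here can therefore differ from those of the 6-group model, which called 1956 genes before and 4170 after OSKM. The other groupings mixed knockdown and control libraries, or the hairpins, so true differences could remain in them. Their counts are therefore not counts of chance calls alone. Before OSKM 1 of 35 splits of the libraries gave as many genes as the real 818 (that split itself; highest other 35), and 7 of 35 gave as many lists as the real 6 (highest other 7), so chance was not excluded for the number of lists before OSKM. After OSKM 1 of 84 splits gave as many genes as the real 2897 (highest other 800) and 3 of 84 as many lists as the real 9 (highest other 11). For the difference of effects 1 of 100 shuffles gave as many genes as the real 342 (highest other 31) and 1 of 100 as many lists as the real 9 (highest other 8). Of 100 regroupings 1 gave as many genes shared by the hairpins after OSKM as the real 2269 (highest other 1623). The designs with 10 splits are too few for a share under 0.05: shSETD2-1 after OSKM (1 of 10, real 3453, highest other 0), shSETD2-3 after OSKM (1 of 10, real 4622, highest other 0), OSKM in control cells (genes 1 of 10, real 6133, highest other 0, and lists 1 of 10, real 14, highest other 10) and the hairpins against each other after OSKM (1 of 10, real 1857, highest other 0).

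The knockdown effect differed between the times in 1183 genes, and the hairpins differed from each other in 1299 genes before OSKM and 1890 after it. Among the genes the difference of effects was -2.35 for PRG4, -1.95 for MYH11, -1.64 for TNXB, -1.56 for TNFRSF11B, -1.48 for RGS5 and -1.47 for PAX8. In the other direction it was 2.16 for DHRS3, 1.80 for NPTX1, 1.80 for ITGB4, 1.71 for SERPINB9 and 1.62 for KIF26A. Among the lists the adjusted p of the difference was 4.43e-08 for interferon, 4.91e-08 for ribosomal proteins, 5.87e-07 for pluripotency, 1.20e-06 for glycolysis and hypoxia, 3.62e-05 for the stress response and 0.000407 for matrix genes. It was 0.0223 for epithelial genes, 0.0242 for p53 targets, 0.0242 for cholesterol synthesis, 0.0410 for S phase and 0.0410 for neural markers. With an estimated correlation only pluripotency passed (adjusted p = 0.0122), and the other 10 lay between 0.111 and 0.447. In 1 library, post-OSKM shSETD2-1 replicate 2, the pair of unnamed IDs took 18.2% of the counts.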

How the results depend on the processing

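Scaling was the setting that moved most counts. Totals by library size include the pair of unnamed IDs, which took up to 18.2% of counts in knockdown libraries and at most 3.59% in controls. With these IDs left out and TMM kept, the split with both hairpins was 870 higher and 1076 lower before OSKM (925 and 1031). After it the split was 1927 and 2232 (1930 and 2240). Library size without these IDs was not run, so their part in the changes below was not tested. With library size only, 1217 genes passed before OSKM with both hairpins (1956 in the report), 734 with shSETD2-3 (1538), 548 for the difference of effects (1183), 609 between the hairpins before OSKM (1299) and 948 after it (1890), and the hairpins shared 350 calls before OSKM (685). With both hairpins as 1 group 845 genes passed before OSKM and 342 for the difference of effects. Without the 3 libraries high in the unnamed IDs, a choice made after the data were seen, 1984 genes passed with shSETD2-3 after OSKM (3865), 582 between the hairpins after OSKM (1890), and the hairpins shared 1338 calls after it (2146). With an estimated correlation 0 of 8 lists passed before OSKM, 7 in place of 12 after it, 9 in place of 15 for OSKM in control cells and 1 in place of 11 for the difference of effects, and fry gave 23 for OSKM in control cells. With each library left out in turn the counts were 1337 to 2162 for shSETD2-1 before OSKM (lowest without its replicate 1), 889 to 1630 for shSETD2-3 (lowest without its replicate 3, and 1015 without replicate 1) and 769 to 1414 between the hairpins before OSKM (lowest without shSETD2-3 replicate 3, and 863 without shSETD2-1 replicate 1). Lists past the test for the difference of effects numbered 6 (without pre-OSKM shSETD2-1 replicate 1) to 15. The interferon list after OSKM ranged from adjusted p = 1.85e-05 without control replicate 3 to 0.705, with its direction turned, without control replicate 1. With library size only the list medians turned sign before OSKM for epithelial (0.01 to -0.05), p53 (0.05 to -0.01) and ribosomal genes (0.01 to -0.06), and after it for S phase (0.06 to -0.02), cholesterol (0.03 to -0.04) and DNA repair (0.02 to -0.06). Of 364 named gene calls 223 held in every setting run for them, and 0 named values turned direction. Both hairpins as 1 group, which was not run for OSKM in control cells, kept 151 of the calls it covered and lost 107.

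With a replicate block 1833 genes passed before OSKM and 4119 after it with both hairpins, 5849 for OSKM in control cells and 1104 for the difference of effects, and SETD2 stood at -1.60 and -1.61. The G2 and M phase list before OSKM did not pass with the block (adjusted p = 0.0588) and the S phase list did (0.0281). Libraries with the same replicate number in different groups correlated, after removing group means, at -0.0454 to 0.0355 over 36 pairs, against -0.0557 to 0.0466 over 70 other pairs. The cause was not tested.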

Other observations

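Some genes moved the same way with each hairpin at both times, 210 higher and 232 lower, and 6 and 11 of these changed at least 2-fold in all 4 comparisons. The genes named in this paragraph were chosen after values were seen. The muscarinic receptor CHRM2 fell by 2.84 and 3.22 on the log2 scale after OSKM (shSETD2-1, then shSETD2-3), and the secreted chitinase-like protein CHI3L1 by 2.92 and 1.85 before OSKM and 2.84 and 2.71 after it. The bone morphogenetic protein BMP6 rose by 1.73 and 1.67 before OSKM. ARL6IP1 rose by 2.07 and 2.14 before and 2.13 and 1.97 after OSKM, and did not differ between the hairpins (adjusted p = 0.846 and 0.389).

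The hairpins also differed in members of some gene lists. Before OSKM 12 of 24 TGF-beta targets and contractile genes were higher with shSETD2-1 than with shSETD2-3 and 2 lower, as in smooth muscle actin ACTA2 (log2 0.69) and the matricellular protein CCN2 (0.69) (adjusted p = 1.51e-05, adjusted p = 0.169 with an estimated correlation). G2 and M phase genes were lower with shSETD2-1 before OSKM (8 of 30, adjusted p = 1.61e-07, adjusted p = 0.395 with an estimated correlation) and higher after it (17 of 30, adjusted p = 2.77e-08, adjusted p = 0.341 with an estimated correlation). After OSKM inflammatory genes were lower with shSETD2-1, 8 of 27, as in the chemokines CCL2 (-1.06) and CXCL8 (-0.93) (adjusted p = 0.000247, adjusted p = 0.0256 with an estimated correlation).

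Hypothesis, written before its test was run: since SETD2 methylates the bodies of transcribed genes, genes with a long span should fall more when it is low. Over 10313 coding genes Spearman's rho between span and log2 fold change was 0.0337 before OSKM (-0.0217 to 0.0853 with each library left out) and -0.0274 after it (-0.0510 to -0.00772). The higher of these, 0.0337, lay above the -0.1 set for the hypothesis, so a link of that strength at both times was not seen. A weaker link is left open, since rho after OSKM stayed below 0 with each library left out.

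Hypothesis, written before its test was run: lower H3K36 methylation lets more non-coding transcripts be made, so that called non-coding genes should rise more often than coding ones. Before OSKM 28 of 48 called non-coding genes (58.3%) were higher, against 47.2% of coding genes, and after it 53.8% against 46.0%. The larger Fisher exact p of the times was 0.144 (0.0748 after OSKM), so the test cannot tell. With shSETD2-3 after OSKM the shares were 61.6% and 48.0% (Fisher exact p = 0.00344), with shSETD2-1 they were 41.9% and 45.8% (Fisher exact p = 0.45), and between the hairpins after OSKM 15.7% of called non-coding genes were higher with shSETD2-1 against 47.4% of coding ones (Fisher exact p = 5.12e-06). Fisher's test counts genes of the same libraries as independent, so these p-values do not measure the spread between libraries. The comparisons by hairpin were not part of the prediction. Strand was not given, so antisense reads could not be told from sense.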
